A study of Mus musculus with 20 samples.

How the data were processed

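RNA sequencing of bulk tumour tissue was analysed for 20 libraries in 5 groups of 4. The PDAC (pancreatic ductal adenocarcinoma) model gave primary tumours, lung metastases and liver metastases of the same 4 mice. The BC (breast cancer) model gave primary tumours and lung metastases of the same 4 mice, from 4T1, a mouse mammary carcinoma line. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with a TruSeq RNA kit, which the labels do not describe as strand-marking. Per the submitters' processing notes the genome build was mm9; the aligner, the counting tool and the annotation are not given in the sources used here. Genes are identified below by the symbols and identifiers in the deposited table, and no coordinates are printed because the reference at hand is of another build.

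The authors deposited 1 table of signal values, gene read counts divided by a scaled library size and multiplied to a level of 1000000. Its column totals ran from 889703 to 1213686, so the values are not plain CPM, the unit the design had assumed. The geometric mean of the column totals was 1000000 over the 12 PDAC columns and 998661 over the 8 BC columns, so the 2 models were scaled separately and every test was made within a model. All values of each column were whole multiples of the value of 1 read within a tolerance of 0.05 reads (100% of values), which recovered the reads. Depth was 15447918 to 28995834 reads in the BC libraries, with the lowest in BC lung metastasis 3, and 20585374 to 44759451 in the PDAC libraries. A single read was worth 0.0337 to 0.0676 in the BC columns. Where a group had 0 reads of a gene, a floor of 3 reads per library was used and the fold is a lower bound; reads carry no molecular identifiers, so floors cover counting error only.

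The table held 37583 rows, and its identifiers belonged to the BC block alone. Identifiers and symbols stood on 15466 rows, 15465 of which held BC values, whereas the PDAC columns held values on all 37583 rows, 22117 of them with no identifier. The PDAC values did not follow the symbols beside them: across rows, which are not independent replicates, Spearman's rho of the BC and PDAC means was 0.1, and within 31 windows of 500 rows it lay between -0.12 and 0.12. PDAC rows were therefore tested as rows without a name. No name was assigned from the order of rows. For this reason gene lists in the PDAC model, named PDAC genes, the genes changed in all 3 metastasis comparisons, the difference between the models and a fit of all 20 libraries were planned and could not be run.

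The test was limma with an intensity trend on log2(value + 1). Rows entered with a value of at least 1 in at least 4 libraries of the model, where the design had said of all 20 libraries; 15533 PDAC rows and 14003 BC genes were tested. Fold changes on this scale understate those of low genes. The PDAC fit held the 12 libraries of 3 groups and the BC fit the 8 libraries of 2 groups, with group means only. A row was called changed at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values below are from limma, or from its camera test for lists, unless another tool is named. For Sirt6 genotype, the mouse was the replicate (2 against 2), using the mean over its 3 tissues and, separately, the mean of its metastases minus its primary tumour.

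Before the data were examined, 29 gene lists with 419 entries were fixed from textbook knowledge, together with the tests, the alternatives and the rule for naming genes. The lists were lung epithelium, hepatocyte, liver non-parenchymal, pancreatic acinar, pancreatic islet, ductal epithelium, skin keratinocyte, adipocyte, skeletal muscle, mesothelium, fibroblast and matrix, endothelium, T and NK cell, B and plasma cell, macrophage, neutrophil, erythroid, immediate early and heat shock, mesenchymal transition, cell cycle, glycolysis, oxidative phosphorylation, glutathione metabolism, oxidative stress response, hypoxia, interferon response, antigen presentation, acute phase, and the Lin28b let-7 axis. In the BC fit 26 lists had at least 5 tested members and were tested with camera at a preset correlation of 0.01; an estimated correlation and fry were alternatives. The naming rule took Sirt6, Trp53, Gstt1 and a further gene that is not reported here; the 6 largest rises and 6 largest falls among called genes outside the lists whose groups did not overlap; and up to 4 members with the smallest p of each list described. No list was chosen by the study on these samples.

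The titles name the mouse of each library, and the series text calls the tumours matched, so the replicate numbers pair tissues of the same animal. Deviations from the group means correlated between same-mouse libraries at a median of 0.02 (range -0.15 to 0.1) for BC lung metastasis and primary, 0.16 (-0.09 to 0.23) for PDAC lung metastasis and primary, 0.12 (0.01 to 0.25) for PDAC liver metastasis and primary, and 0.21 (0.08 to 0.43) for PDAC liver and lung metastases. The fit was repeated with the mouse as a block. Within a group the 4 libraries come from separate mice.

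Other alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 in 4 libraries, median-ratio scaling, array weights, only the 2 groups compared, a genotype covariate, a fold of at least 2, and leaving out each library. The design had named the edgeR quasi-likelihood test in place of limma if the values proved to be whole counts. The deposited values were scaled, and limma was kept as the main test although whole reads could be recovered. On the recovered reads, edgeR and DESeq2 were run as alternatives after the data were seen. On simulated values with 200 changed rows, the BC fit of 14003 genes recovered 10% of 2-fold and 61% of 4-fold changes. Recovery of 4-fold changes among 15533 PDAC rows was 27% for lung metastasis against primary, 49% for liver metastasis against primary and 31% for liver against lung metastasis, and of 2-fold changes 1%, 1% and 4%. At 2 mice per genotype it was 0% for both sizes. The work used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.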

Results

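The libraries measured messenger RNA of whole tumour tissue, so every value is a mixture of tumour cells and the other cells in the sampled piece. The series asks which genes differ between primary tumours and the metastases of the same mice, in a pancreatic (PDAC) and a breast (BC) cancer model. The PDAC mice carried a floxed copy of p53 with a Cre recombinase named for p48, and 2 of the 4 were also floxed for SIRT6, a chromatin deacylase. They were sampled at 21.14 to 31.29 weeks. The BC tumours derived from 4T1 cells and were sampled at 28 days. Depth was 15447918 to 28995834 reads per BC library and 20585374 to 44759451 per PDAC library. Values below are normalised read counts, per 1000000 reads of a scaled library, as mean ± SD over 4 mice unless stated otherwise.

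Lung metastases of the BC model carried more lung epithelial, mesothelial, neutrophil and red-cell transcripts than the primary tumours of the same mice. Sftpc, which encodes surfactant protein C of alveolar type 2 cells, stood at 5034 ± 2233 in lung metastases and 1.41 ± 0.432 in primary tumours (log2 change 10.95, SE 0.282, adjusted p = 1.63e-08). Camp, which encodes the neutrophil granule peptide cathelicidin, stood at 349 ± 235 against 5.06 ± 3.85. Gstt1, a theta-class glutathione transferase, was 5.26-fold higher (ratio of the means). Rgs5, a regulator of G protein signalling known from pericytes, fell from 78.7 ± 46.9 to 3.73 ± 1.11. In all, 1279 of 14003 genes changed, 1005 higher and 274 lower in lung metastases; on the log2(value + 1) scale, 1120 of them changed by at least 2-fold and 119 rose by over 16-fold, while 0 fell by as much.

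The lung epithelium list showed the largest shift. Of its 16 tested members 15 rose (16 when adjusted over the list alone), with a median log2 change of 6.83 (adjusted p = 3.05e-30; adjusted p = 0.137 with an estimated correlation). Besides Sftpc, the surfactant genes Sftpa1 (851 ± 449 against 0.284 ± 0.184) and Sftpd (264 ± 94.9 against 0.082 ± 0.076) and Ager, a receptor of alveolar type 1 cells (593 ± 279 against 2.84 ± 0.517), had the smallest p. The list took 0.756% to 3.48% of all reads in the lung metastases and 0.002% to 0.005% in the primary tumours. Its mean log2 value was 8.82 in BC lung metastasis 3, 7.82 in 1, 7.28 in 2 and 6.68 in 4. All 8 mesothelium genes rose, with a median of 3.75, or 4.99 with the 3 members at 0 in primary tumours set to their bound (adjusted p = 6.74e-12; adjusted p = 0.137 with an estimated correlation). Nkain4 was at least 147-fold higher in lung metastases (16.4 ± 6.78) and Rspo1, a Wnt signalling agonist, at least 102-fold (11.3 ± 6.27), against 0 reads in the primary tumours. The uroplakin gene Upk1b rose from 0.237 ± 0.279 to 31.9 ± 18.9. Upk3b stood at 61.7 ± 48.5 against 1 read over the 4 primary tumours. The mesothelium list took 0.019% to 0.055% of reads in lung metastases and 0.006% to 0.015% in primary tumours, where 1 member reached a mean of 1.

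The 6 largest rises outside the lists were of Cxcl15, a chemokine of lung epithelium, Inmt, an indolethylamine N-methyltransferase, Sec14l3, Aldh1a1, a retinal dehydrogenase, Cldn18, a tight junction claudin, and Clic5, a chloride intracellular channel protein. Cxcl15 stood at 359 ± 144 in lung metastases and 0.213 ± 0.332 in primary tumours (log2 change 8.12, SE 0.369, adjusted p = 1.16e-06). Inmt stood at 658 ± 508 against 1.59 ± 1.66, Sec14l3 at 225 ± 176 against 0.072 ± 0.065 and Aldh1a1 at 233 ± 151 against 0.488 ± 0.195. Cldn18 stood at 150 ± 93.8 against 0.037 ± 0.003 and Clic5 at 168 ± 157 against 0.306 ± 0.387. All 6 were highest in BC lung metastasis 3 and lowest in BC lung metastasis 4, as was the lung epithelium mean. Normal lung in the sampled pieces as a source of these 6 rises was not separated from a change in tumour cells.

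Neutrophil genes rose as a group, 12 of 13 (13 adjusted over the list alone), with a median of 4.97 (adjusted p = 3.8e-16; adjusted p = 0.137 with an estimated correlation). Ngp (998 ± 884 against 17.6 ± 9.48), Ltf, which encodes lactoferrin (737 ± 624 against 13.9 ± 7.27), and the surface marker Ly6g (51.9 ± 44.8 against 0.448 ± 0.597) rose with Camp. The neutrophil list took 0.823% to 3% of reads in lung metastases and 0.026% to 0.136% in primary tumours, and its mean was highest in BC lung metastasis 3, where the lung epithelium mean was highest too. The 5 tested erythroid genes all rose, with a median of 5.41 (adjusted p = 3.46e-09; adjusted p = 0.137 with an estimated correlation). Hbb-b1 stood at 3396 ± 2465 against 67.4 ± 43.2, and Hbb-b2, Hba-a1 and Hba-a2 also rose. Hba-a1 and Hba-a2 are close copies of each other, as are Hbb-b1 and Hbb-b2, so the separate values within each pair of these globin genes are uncertain. Their list mean was also highest in BC lung metastasis 3. Of 15 T and NK cell genes 2 rose (3 adjusted over the list alone), Gzma (9.3 ± 1.98 against 1.47 ± 0.828) and Cd3d (11.3 ± 5.36 against 2.2 ± 0.929), and the list had a median of 0.84 (adjusted p = 0.00311; adjusted p = 0.581 with an estimated correlation). Its mean log2 value was higher in the metastasis of mice 1 to 3 and not of mouse 4 (1.69 against 1.8). Cd5 stood at 3.12 ± 1.75 against 0.671 ± 0.424 and Nkg7 at 6.02 ± 3.36 against 2.19 ± 1.16, without passing; Cd5 passed with array weights (adjusted p = 0.0134) and DESeq2 (0.0121; 0.0121 to 0.161 over its 16 alternatives).

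Of 15 endothelial genes 6 rose (7 adjusted over the list alone) and 0 fell, with a median of 1.37 (adjusted p = 2.01e-05; adjusted p = 0.581 with an estimated correlation and 0.124 with fry; 8.51e-09 to 0.581 over its 13 alternatives). The angiopoietin receptor gene Tek stood at 95 ± 77.1 against 6.81 ± 3.76 and the VEGF receptor gene Kdr at 84.6 ± 54.3 against 15.8 ± 8.03. Vwf (146 ± 174 against 12.1 ± 8.62) and Cldn5 (260 ± 128 against 60.4 ± 61.6) passed as well. The call of Vwf ended without BC primary tumor 1, 3 or 4 (adjusted p 0.0612 to 0.0634; 1.02e-05 to 0.0634 over its 17 alternatives), and that of Cldn5 without BC lung metastasis 1 or BC primary tumor 1, 3 or 4 (0.0618 to 0.0694) or with edgeR (0.0788; 0.00142 to 0.0788 over its alternatives). The endothelial mean log2 value did not rise in every mouse. It was 6.16 against 4.09 in mouse 1, 5.79 against 5.83 in mouse 2, 7.39 against 4.36 in mouse 3 and 5.36 against 4.64 in mouse 4, metastasis against primary tumour, so the groups overlapped.

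Of 6 tested acute phase genes 4 rose, over all genes and adjusted over the list alone, with a median of 2.7 (adjusted p = 0.000121; adjusted p = 0.149 with an estimated correlation). Itih4, an inter-alpha-trypsin inhibitor chain, stood at 23.3 ± 4.09 against 0.28 ± 0.132, the serum amyloid gene Saa3 at 780 ± 216 against 110 ± 107 and the haptoglobin gene Hp at 638 ± 453 against 75.5 ± 47.3. Lbp, which binds lipopolysaccharide, stood at 58.2 ± 29.5 against 12.3 ± 9.09, and its call ended without BC primary tumor 4 (adjusted p = 0.0511; 0.000258 to 0.0511 over its 17 alternatives). Of 10 immediate early and heat shock genes 4 rose, adjusted over the list alone as well, with a median of 0.62 (adjusted p = 0.00526; adjusted p = 0.554 with an estimated correlation). Fos stood at 109 ± 57.4 against 19.4 ± 15.1 and the phosphatase gene Dusp1 at 182 ± 88.9 against 30.9 ± 33.2. Dusp1 lost its call with edgeR on the recovered reads (adjusted p = 0.0514; 0.00058 to 0.0514 over its 17 alternatives). Jun (227 ± 37.3 against 130 ± 15.2) was not past the threshold without BC primary tumor 3 or 4 (adjusted p 0.0572 and 0.061; 4.84e-05 to 0.061 over its alternatives). Egr1 (63.2 ± 24 against 22.7 ± 11.8) was not past it without BC lung metastasis 1, 2 or 4 or BC primary tumor 1, 3 or 4 (0.0509 to 0.0915; 0.00136 to 0.0915 over its alternatives). The list itself was not called without BC lung metastasis 4 (adjusted p = 0.136; 0.000679 to 0.554 over its 13 alternatives).

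Gstt1, the gene named in advance among those that conjugate glutathione, stood at 20.8 ± 8.09 in lung metastases and 3.96 ± 2.62 in primary tumours (log2 change 2.24, SE 0.426, adjusted p = 0.00865). It was higher in the metastasis of all 4 mice, at 19.4 against 5.21 in mouse 1, 18.1 against 7.02 in mouse 2, 32.4 against 2.33 in mouse 3 and 13.5 against 1.3 in mouse 4. The glutathione metabolism list as a whole had 7 of 24 members higher and 2 lower (8 and 2 adjusted over the list alone), with a median of 0.6 (adjusted p = 0.000998; adjusted p = 0.137 with an estimated correlation). Gsta3, an alpha-class transferase, stood at 33.6 ± 23.2 against 0.45 ± 0.224, and the secreted glutathione peroxidase gene Gpx3 at 509 ± 374 against 76.9 ± 34.4. Gpx2 stood at 7.17 ± 5.37 against 2 reads over the 4 primary tumours. Gsto1, an omega-class transferase, fell from 139 ± 29.3 to 62.1 ± 13.3. Glutathione transferase genes belong to families of similar copies, so reads can be split between them. In the lung metastases Gstt1, Gsta3 and Gpx3 each ranked in the order of the lung epithelium mean. They were highest in BC lung metastasis 3, the library with the most lung epithelium signal, followed by 1, 2 and 4. Gpx2 did not keep that order and was highest in BC lung metastasis 1 (12.3, against 11.4 in 3). Lung tissue as a source of these rises was not tested for this list.

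Sirt6 and Trp53, also named in advance, did not pass the test in the BC model. Sirt6 stood at 12.3 ± 2.78 in lung metastases and 15.3 ± 2.27 in primary tumours (adjusted p = 0.489). Trp53 stood at 37.1 ± 5.64 against 57.2 ± 6.34 with no overlap between groups (log2 change -0.62, adjusted p = 0.0512). It passed with array weights (adjusted p = 0.0339), with DESeq2 on the recovered reads (0.00585) and without BC lung metastasis 3 (0.0463), and not with edgeR or with the mouse as a block (0.09; 0.00585 to 0.136 over its 17 alternatives).

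**Figure D1:**
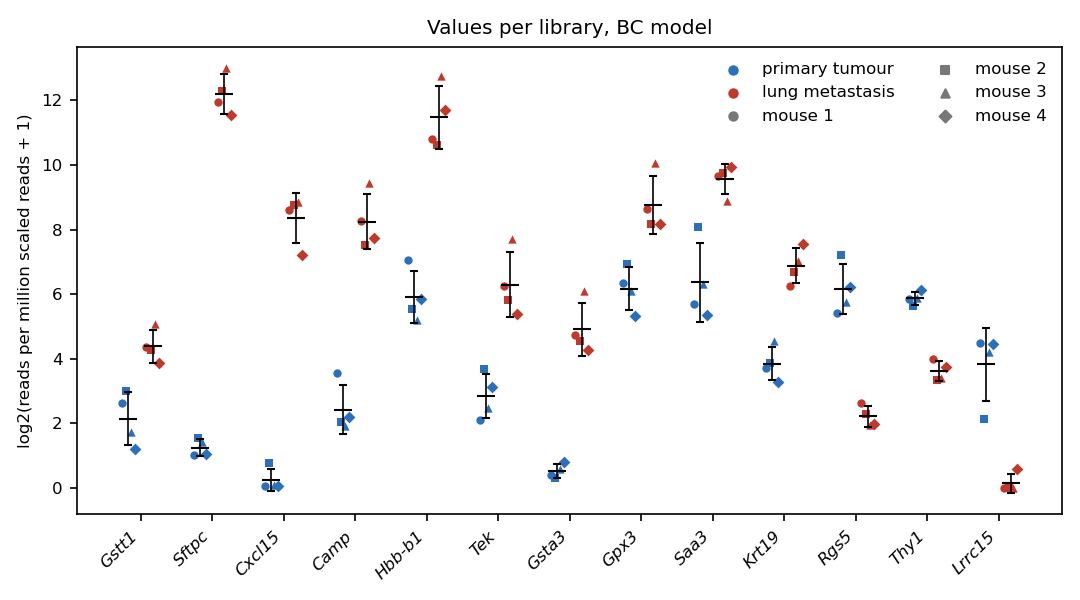
Values of 13 genes in the 8 BC libraries on a log2(value + 1) scale; each point is a library, its shape gives the mouse, and bars give the mean and SD of 4 libraries. The lung metastases lie above the primary tumours of all mice for Gstt1, Sftpc, Cxcl15, Camp, Hbb-b1, Tek, Gsta3, Gpx3, Saa3 and Krt19, and below them for Rgs5, Thy1 and Lrrc15.

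The 6 largest falls outside the lists were of Rgs5, the granzyme genes Gzmd, Gzmf and Gzmg, Lrrc15, a leucine-rich repeat membrane protein of matrix fibroblasts, and Crabp1, a retinoic acid binding protein. Rgs5 fell by 3.94 on the log2 scale (SE 0.37, adjusted p = 0.000169). Lrrc15 fell from 15.8 ± 8.45 to 0.126 ± 0.252. Crabp1 had 0 reads in the 4 lung metastases against 14.7 ± 8.87 in primary tumours, at least 106-fold lower. Gzmg stood at 0.757 ± 0.727 against 37.7 ± 50, Gzmf at 0.204 ± 0.319 against 31.8 ± 47 and Gzmd at 0.503 ± 0.102 against 28.9 ± 42.8. The 3 granzyme genes are close copies of each other and can share reads. Gzmd was not past the threshold without BC lung metastasis 1 (adjusted p = 0.0541) or with a pseudocount of 5 (0.0884; 8.1e-10 to 0.0884 over its 16 alternatives), nor Gzmf without BC lung metastasis 1, 2 or 4 or BC primary tumor 3 or 4 (0.0513 to 0.081) or with a pseudocount of 5 (0.103; 0.000362 to 0.103 over its alternatives).

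Both called lists that fell did so with few members past the gene test. Of 12 macrophage genes 1 fell and 0 rose, over all genes and adjusted over the list alone, and all 12 had negative changes, with a median of -0.89 (adjusted p = 0.00192; adjusted p = 0.551 with an estimated correlation). Mouse 2 ran the other way, with a mean log2 value of the list of 7.19 in the metastasis and 6.72 in the primary tumour, and Mrc1 at 256 against 161, C1qa at 431 against 358 and Cd163 at 21.2 against 11.6. Trem2, a lipid receptor of macrophages, stood at 30.1 ± 16.8 against 84.3 ± 27.2 (adjusted p = 0.0334, and 0.0548 with the mouse as a block). Its call also ended without BC lung metastasis 1 or BC primary tumor 1, 3 or 4 (0.0836 to 0.11) and with edgeR (0.00577 to 0.11 over its 17 alternatives). Unlike the list mean, Trem2 was lower in the metastasis of mouse 2 too, at 50.9 against 57.5. The mannose receptor gene Mrc1 stood at 149 ± 72.7 against 300 ± 98.2, the complement gene C1qa at 345 ± 151 against 734 ± 253 and the haemoglobin scavenger receptor gene Cd163 at 11.8 ± 8.96 against 32.6 ± 17.7, none past the threshold. With array weights all 3 passed: Mrc1 at an adjusted p of 0.0297, C1qa at 0.0342 (0.0342 to 0.311 over its alternatives) and Cd163 at 0.0307 (0.0307 to 0.341). Mrc1 also passed without BC lung metastasis 2 or BC primary tumor 2 (adjusted p 0.0285 and 0.0336; 0.0285 to 0.249 over its alternatives). Of 13 mesenchymal transition genes 1 fell, adjusted over the list alone as well, with a median of -0.39 (adjusted p = 0.0445; adjusted p = 0.269 with an estimated correlation). In mouse 2 the mean log2 value of the list was 6.32 in the metastasis and 6.31 in the primary tumour. That list was not called without BC lung metastasis 2 or BC primary tumor 3 or 4 (0.0522 to 0.0661; 0.0131 to 0.269 over its 13 alternatives). Its called member was the transcription factor gene Twist2, at 0.548 ± 0.482 against 3.89 ± 2.16 (adjusted p = 0.0329, and 0.0544 with the mouse as a block), whose call also ended without BC lung metastasis 1, 2 or 4 or BC primary tumor 3 or 4 (0.0577 to 0.114), with a pseudocount of 0.1 or 5 and with edgeR (0.145; 0.00535 to 0.145 over its 16 alternatives). The fibronectin gene Fn1 stood at 2070 ± 1155 against 4743 ± 1154, Tgfb1 at 83.2 ± 16.9 against 121 ± 6.12 and Mmp14 at 314 ± 129 against 529 ± 113. With array weights all 3 passed (adjusted p 0.0156, 0.0158 and 0.0305; 0.0305 to 0.345 for Mmp14 over its alternatives). Fn1 also passed with DESeq2 (0.0265) and without BC lung metastasis 4 (0.0493; 0.0156 to 0.26 over its alternatives), and Tgfb1 without BC lung metastasis 3 (0.0241; 0.0158 to 0.201 over its alternatives).

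**Figure D2:**
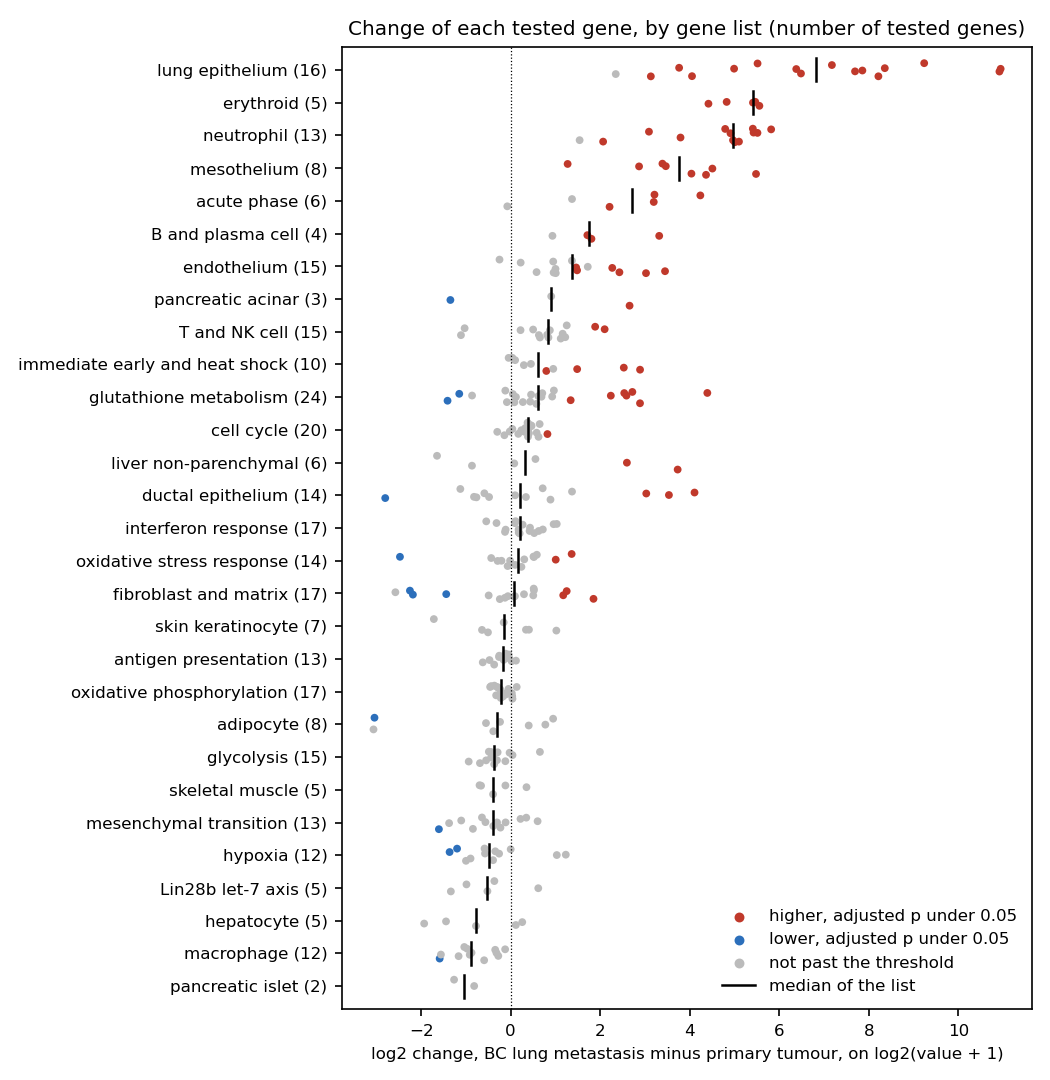
Log2 change of each tested gene of the 29 lists, BC lung metastasis minus primary tumour; points are genes, coloured where the adjusted p is under 0.05, and bars mark list medians. Medians lie at 6.83 for lung epithelium, 5.41 for erythroid, 4.97 for neutrophil and 3.75 for mesothelium, and between -0.89 and 0.91 for every list below endothelium except pancreatic islet, at -1.04.

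In all, 11 of 26 lists were called, 9 up and 2 down, and 0 with an estimated correlation, under which 6 lists had an unadjusted p under 0.05; fry called 7. These were lung epithelium, mesothelium, neutrophil, erythroid, glutathione metabolism, acute phase and, outside the 11, liver non-parenchymal. Among the other splits of the 8 BC libraries into 4 and 4, camera called a median of 9 lists and up to 16. The number of lists called therefore does not exclude chance. Cell cycle (median 0.38, adjusted p = 0.0509), glycolysis (median -0.38, adjusted p = 0.0523) and hypoxia (median -0.48, adjusted p = 0.0523) lay just above the threshold. With the mouse as a block, cell cycle (adjusted p = 0.0478; 1.38e-07 to 0.784 over its 13 alternatives) and glycolysis (adjusted p = 0.0497; 0.00501 to 0.647) passed it. With median-ratio scaling cell cycle (0.0349), glycolysis (0.0479) and hypoxia (0.0473) all passed, and with a pseudocount of 0.1 cell cycle did. Cell cycle also passed without BC lung metastasis 3 or BC primary tumor 1 or 3 (1.38e-07 to 0.0414), glycolysis without BC lung metastasis 4 or BC primary tumor 1, 3 or 4 (0.00501 to 0.0397), and hypoxia without BC lung metastasis 1 or 4 or BC primary tumor 1, 3 or 4 (0.0243 to 0.0463; 0.0243 to 0.591 over its alternatives). Hepatocyte (adjusted p = 0.262), liver non-parenchymal (0.323; 0.0234 with fry, and 0.0234 to 0.591 over its alternatives), ductal epithelium (0.332), skin keratinocyte (0.859), adipocyte (0.667), skeletal muscle (0.59) and fibroblast and matrix (0.859) were not called by camera. Nor were oxidative phosphorylation (0.18), oxidative stress response (0.262), interferon response (0.262), antigen presentation (0.353; 0.0243 without BC lung metastasis 1, and 0.0243 to 0.964 over its alternatives) and the Lin28b let-7 axis (0.18). Fewer than 5 members were tested for B and plasma cell, pancreatic acinar and pancreatic islet genes.

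The values of the groups did not overlap for 1241 of the 1279 called genes, and for 17.9% of all tested genes where chance gives 2.86%. BC lung metastasis 3 was the shallowest library, and its 10 most abundant genes took 13.4% of reads against 3.9% to 5.2% in the other lung metastases. The count was 1551 without that library. It was 851 without BC primary tumor 1, 852 without BC primary tumor 3 and 711 without BC primary tumor 4. The number of falls moved more than the total, to 141, 122 and 84 without those primary tumours, and to 747 with array weights and 565 with DESeq2, against 274 as reported.

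The PDAC model is reported by row, since its values are not paired with the gene symbols in the table. The row with the symbol Actb, a cytoskeletal actin gene that is abundant in most tissues, averaged 4223 over the BC libraries and lay between 5.76 and 13.3 in the PDAC libraries. The row of the translation factor gene Eef1a1 averaged 5991 in BC and lay between 5.86 and 20.2 in PDAC, and that of the beta-2-microglobulin gene B2m averaged 1475 against 0 to 6.72. The expression of Sirt6 could therefore not be checked against the genotype labels, and no PDAC value is given for Trp53 or Gstt1. Normal lung or liver tissue in the sampled PDAC metastases could not be assessed either, since no gene list could be run. The PDAC counts and largest rises below may include such tissue.

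**Figure D3:**
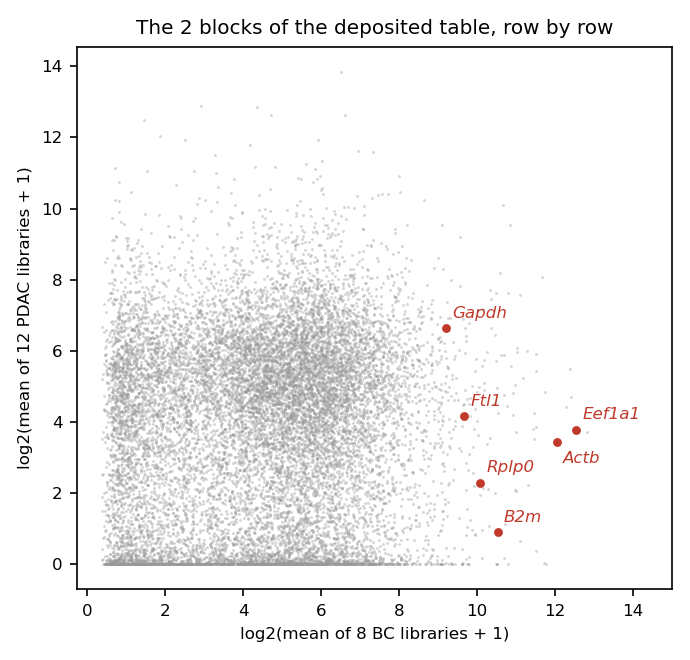
Mean of the 12 PDAC libraries against mean of the 8 BC libraries on the same row of the deposited table, both as log2(mean + 1), for the 15465 rows with BC values; each grey point is a row. Rows with the symbols of 6 abundant genes are marked in red, and the cloud has no diagonal (Spearman's rho 0.1 across rows).

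PDAC lung metastases differed from the primary tumours of the same mice in 2524 of 15533 tested rows, 1721 higher and 803 lower; on the log2(value + 1) scale, 158 rows rose and 3 fell by over 16-fold. The row with the largest rise stood at 44242 ± 24529 in lung metastases and 3.25 ± 0.506 in primary tumours (log2 change 13.18, SE 0.38, adjusted p = 1.2e-09), and it stayed at 4.27 ± 2.24 in liver metastases. The second largest stood at 19187 ± 14605 against 1.66 ± 0.706. The largest fall was from 162 ± 169 to 3.79 ± 1.28 (adjusted p = 0.000811). The most abundant row took 2.41% to 7.27% of reads in lung metastases and 0.98% to 1.9% in primary tumours. The count was 1457 without PDAC lung metastasis 6 and 1556 without PDAC lung metastasis 15, with 341 and 385 rows lower. With array weights 1673 rows were lower and with DESeq2 1328, against the 803 reported, so the number of falls depended on the libraries and the test.

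PDAC liver metastases differed from the primary tumours in 599 rows, 575 higher and 24 lower, and 231 rows rose by over 16-fold. The number of falls depended on the test: DESeq2 on the recovered reads called 991 rows higher and 207 lower, and edgeR 446 and 11. The row with the largest rise stood at 22001 ± 13404 in liver metastases and 1.93 ± 0.652 in primary tumours (log2 change 12.48, SE 0.825, adjusted p = 2.31e-06), and at 12.4 ± 18.9 in lung metastases. The second stood at 6883 ± 5587 against 0.401 ± 0.068. Values of the groups did not overlap for 7.9% of all tested rows, 944 higher and 288 lower, where chance gives 2.86%.

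Between the metastatic sites, 2035 rows differed, 858 higher in liver and 1177 higher in lung metastases. This split was not kept by other tests on the recovered reads, with 602 and 595 by edgeR and 1363 and 1410 by DESeq2. The 2 largest differences in each direction were the rows with the largest rises named for each site. By over 16-fold, 213 rows were higher in liver and 111 in lung metastases. The count was 1242 without PDAC lung metastasis 6 and 1341 without PDAC lung metastasis 15.

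Some rows passed in both comparisons with the primary tumours. Across rows, which are not independent replicates, the 2 sets of log2 changes correlated at 0.31, and 68% had the same sign. Both comparisons use the same 4 primary tumours, and 100 simulations of unchanged groups against them gave a correlation of 0.5 and 66.8% of the same sign. The covariance was 0.379 against 0.137 in the simulations, a difference of 0.241. The simulated libraries were drawn independently, so they leave out any effect of both metastases coming from the same mice. Rows higher in both numbered 145 and rows lower in both 15, and 3 rows changed in opposite directions. The simulations, in which no row changes, gave 0 rows in the same direction in both. They do not show how many rows unrelated changes at each site would share. Independent lists of these sizes would share 63.7 rows higher and 1.2 lower, a count that leaves out the shared primary tumours. With 2 primary tumours used for each comparison, the correlation was 0.15 to 0.22, the covariance 0.205 to 0.294, and 9 to 13 rows were higher in both. Those fits had fewer libraries and so less power, so their smaller overlap cannot be put down to the shared primary tumours alone.

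For Sirt6 genotype, limma called 0 rows on the means over 3 tissues (smallest adjusted p = 0.131) and 0 rows on metastases minus primary (smallest adjusted p = 0.996), with 2 mice per genotype. A fit of the 12 single libraries with the mouse as a random effect called 5 rows. Its estimated correlation within a mouse was 0.058, so it counted the 3 tissues of a mouse as nearly independent. Genotype belongs to the mouse, so these 5 calls rest on fewer replicates than that fit assumed. These rows carry no name. At an unadjusted p under 0.05 there were 1196 and 507 rows, where chance gives 777. The floxed mice were sampled at 31.29 and 27.71 weeks and the others at 28 and 21.14 weeks. On simulated data with 15533 rows this design recovered 0% of 4-fold changes, so differences of that size were not detectable.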

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

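Of 208 sets of 4 values, 30 held a library far from the other 3 by Dixon's test of the gap over the range. Chance gives about 1 in 20 for normally distributed values. Gene values were tested unlogged, where high values stand out more easily, so that rate is no measure of chance here. A set with a single value above 0 is always flagged, as for Lrrc15, Upk3b, Pax5 and Rbpjl. BC lung metastasis 3 and BC primary tumor 2 recurred. BC lung metastasis 3 was highest for Vwf at 406 (others 32.1 to 77.1), Ngp at 2306 (448 to 762), Ly6g at 119 (26.3 to 36), Hba-a2 at 772 (148 to 241), Hba-a1 at 1479 (149 to 289), Gsta3 at 68.1 (18.3 to 25.6), Gpx3 at 1064 (286 to 398) and Cd79b at 8.99 (3.36 to 4.13), and its 10 most abundant genes took 13.4% of reads. It was lowest for C1qa at 120 (405 to 431) and for the mean log2 value of the mesenchymal transition list, 5.79 (6.26 to 6.32).

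BC lung metastasis 4 was highest for Jun at 283 (205 to 210), for the mean log2 value of the immediate early and heat shock list at 6.44 (5.43 to 5.48) and for Lrrc15 at 0.5, with 0 in the other 3. BC primary tumor 2 was highest for Gzmg at 112 (5.72 to 19.2), Gzmf at 102 (1.51 to 15.3), Gzmd at 92.9 (4.33 to 11.5), Lbp at 25.9 (6.32 to 8.66), Fos at 41.7 (9.17 to 14.1), Pdk1 at 113 (62.8 to 71.2), Muc1 at 7.77 (1.59 to 1.99) and Cxcl15 at 0.71 (0.04 to 0.07), and lowest for C1qa at 358 (819 to 912). It was also the only primary tumour with reads of Pax5, at 0.28, and Upk3b, at 0.04, and BC primary tumor 4 the only 1 with reads of Rbpjl, at 0.28. BC primary tumor 1 was highest for Camp at 10.8 (2.76 to 3.59), Ngp at 31.7 (11.5 to 14.6), Hba-a1 at 15 (4.33 to 6.07) and Itih4 at 0.48 (0.2 to 0.24).

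The lung epithelium list took 0.756% to 3.48% of reads in BC lung metastases and 0.002% to 0.005% in primary tumours. The sampled metastases thus held transcripts of lung epithelium. The other genes higher in BC lung metastases may also reflect normal lung in the sampled pieces, and this was weighed with the lung epithelium list. Its most abundant gene, Sftpc, averaged 5034 in lung metastases, and 7 of its 16 members reached a mean of 1 in primary tumours too. For the 6 called endothelial genes, the median Spearman rho with the lung epithelium mean over the 4 lung metastases was 1, above the 0.8 of the best of the other 23 orders, which is in line with lung tissue as a source, over only 4 libraries. For the 12 called neutrophil genes the median rho was 0.8 and another order reached 1, and for the 927 called genes outside the lists it was 0.8 with another order also at 0.8, so 4 libraries leave both open. The epithelial genes Epcam, Krt8 and Krt18 were chosen after their values were seen, and no test of the share of tumour cells was made with them. Epcam, which encodes an epithelial adhesion molecule, stood at 65.1 against 89.2 in mouse 1, 30.2 against 118 in mouse 2, 38.9 against 104 in mouse 3 and 109 against 180 in mouse 4, metastasis against primary tumour (adjusted p = 0.0932; 0.0373 with the mouse as a block, 0.018 with array weights, 0.0149 without BC lung metastasis 4, and 0.0149 to 0.257 over its 17 alternatives). Krt8 and Krt18 did not pass (adjusted p = 0.519 and 0.367) and were lowest in BC lung metastasis 3, at 225 and 196, against 620 to 1462 and 554 to 1166 in the other 3. Of the 927 genes, 84.6% were highest in BC lung metastasis 3, against 34.8% of genes not called; a difference between metastasis and primary tumour cells, and immune cells that accompany a metastasis, were not tested and stay open.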

How the results depend on the processing

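The use of recovered reads (100% of values whole) and DESeq2 were added after the data were seen. For whole counts the design had named edgeR in place of limma, and limma was kept. In each comparison edgeR called fewer than limma. All other settings were planned. Changed genes or rows numbered, in the order PDAC lung against primary, PDAC liver against primary, BC lung against primary, and PDAC liver against lung metastasis: 2524, 599, 1279 and 2035 as reported; 3020, 651, 1112 and 2448 with the mouse as a block, which shared 2421, 559, 1025 and 1940 with them; 1627, 457, 1114 and 1197 with edgeR; 3503, 1198, 2345 and 2773 with DESeq2; 4203, 884, 2283 and 4027 with array weights. Leaving out each library gave 1457 to 2687, 427 to 796, 711 to 1603 and 1242 to 2360. Counts moved by over 1.5 times without PDAC lung metastasis 6 (1457 and 1242) or 15 (1556 and 1341) and without BC primary tumor 1 (851), 3 (852) or 4 (711). With only the 2 groups compared, 396 rows changed between PDAC liver metastasis and primary. The choice of test moved counts by over 1.5 times as well. Array weights did so for PDAC lung against primary (4203), BC (2283) and PDAC liver against lung metastasis (4027). DESeq2 did so for PDAC liver against primary (1198) and BC (2345). With edgeR, PDAC lung against primary (1627) and PDAC liver against lung metastasis (1197) moved. All remaining settings stayed within 1.5 times of each count. The cause of these shifts was not tested.

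Genotype calls were 0 on means and 0 on metastases minus primary. The fit of single libraries with the mouse as a random effect, which counted tissues of a mouse as nearly independent, called 5. Leaving out a mouse leaves a lone mouse in its arm, so those counts are not given. Lists called were 11 as reported, 10 to 14 without each library, 13 with the mouse as a block, 0 with an estimated correlation and 7 with fry, 6 of them among the 11.

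No named gene or list changed direction while called. Over settings that keep all libraries, a gene's call was kept or stayed absent in 1115 cases, ended in 16 and appeared in 31; without each library the numbers were 974, 60 and 22. For lists they were 107, 16 and 7, and without each library 191, 4 and 13. Apart from Trem2, Twist2, Top2a and Cela1, which lost the call, Lgals7 and Epcam, which gained it, and the cell cycle and glycolysis lists, the block changed no other call. Depth limits genes near 3 reads per library, 0.101 to 0.203 in the BC columns. Gene lists in the PDAC model, the 3-way overlap, the difference between models and the fit of 20 libraries were not run, because PDAC rows are not paired with names.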

Other observations

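The rank correlation of the PDAC and BC means was examined as a test only after its value was seen; the other tests below were chosen before their results. Epithelial genes differed within the ductal epithelium list, of whose 14 members 3 rose and 1 fell in BC lung metastases (3 and 3 adjusted over the list alone). Krt19 stood at 123 ± 48 against 14.1 ± 5.72 in primary tumours (adjusted p = 0.000337) and Muc1 at 68.6 ± 34.8 against 3.29 ± 2.99, whereas the claudin gene Cldn4 fell from 114 ± 41 to 20.1 ± 17. Over the lung metastases Muc1 ranked in the order of the lung epithelium mean, and Krt19 did not. Of 17 fibroblast and matrix genes 3 rose and 3 fell (3 and 4 adjusted over the list alone). Thy1 fell from 57.8 ± 8.29 to 11.5 ± 2.7, and Loxl1 (55.6 ± 14 against 14.6 ± 3.86) and the decorin gene Dcn (142 ± 49.5 against 60 ± 6.61) rose. Postn, which encodes periostin, stood at 59 ± 22.3 against 301 ± 147, a call that ended without BC primary tumor 1, 3 or 4 (adjusted p 0.0557 to 0.0622; 1.8e-05 to 0.0622 over its 17 alternatives).

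Of 4 tested B and plasma cell genes 3 rose (4 adjusted over the list alone): Igj at 32.8 ± 30.4 against 1.87 ± 1.91, the B cell factor gene Pax5 at 2.92 ± 1.4 against 0.069 ± 0.138 and Cd79b at 5.1 ± 2.61 against 0.774 ± 0.294. Of 6 tested liver non-parenchymal genes 2 rose and 0 fell (2 and 2 adjusted over the list alone). Lrat, an enzyme of retinoid storage, rose from 2.24 ± 1.42 to 42.9 ± 23.6, and Cd5l was at least 48-fold higher in lung metastases (5.34 ± 2.33). Folr2 stood at 10.5 ± 7.5 against 32.8 ± 14.9 (adjusted p = 0.0546), and passed with array weights, with DESeq2 and without BC lung metastasis 2 or BC primary tumor 2 (0.0157 to 0.165 over its 17 alternatives). Fcna, at 22.9 ± 8.23 against 43 ± 18.5 (adjusted p = 0.154), passed with array weights only (0.0318 to 0.355 over its alternatives). Rbpjl rose to 6.59 ± 4.32. Cela1 stood at 4.71 ± 2.04 against 13.1 ± 3.22, a call that ended without BC lung metastasis 1 or BC primary tumor 2, 3 or 4 (adjusted p 0.0691 to 0.0951) and with the mouse as a block (0.0548; 0.0033 to 0.0951 over its 17 alternatives). Of 14 oxidative stress response genes 2 rose and 1 fell, adjusted over the list alone as well. Taldo1, of the pentose phosphate pathway, rose from 164 ± 17.7 to 333 ± 65.7. G6pdx stood at 147 ± 86 against 50.7 ± 4.24, not past the threshold without BC lung metastasis 1 or BC primary tumor 1, 3 or 4 (0.0525 to 0.0647; 0.0004 to 0.0647 over its alternatives), and the cystine transporter gene Slc7a11 at 15.9 ± 11.5 against 93.1 ± 73.8, not past it without BC lung metastasis 2 or BC primary tumor 2, 3 or 4 (0.0619 to 0.0947) or with edgeR (0.000898 to 0.0947 over its alternatives). Of 12 hypoxia genes 0 rose and 2 fell (1 and 5 adjusted over the list alone). Vegfa, which encodes a vascular growth factor, stood at 164 ± 98.2 against 64.2 ± 23.8 (adjusted p = 0.0643), and passed with array weights, with DESeq2 and without BC lung metastasis 3 or 4 or BC primary tumor 2 (0.00389 to 0.18 over its 17 alternatives). Pdk1 stood at 34.2 ± 11.4 against 78.9 ± 23, not past it without BC lung metastasis 2 or BC primary tumor 4 (0.0512 each; 0.00172 to 0.0512), and Egln3 at 96.5 ± 38.4 against 250 ± 110, not past it without BC lung metastasis 2 or 4 or any primary tumour (0.0503 to 0.141), nor with a pseudocount of 5, a filter of 5 or edgeR (0.00535 to 0.141 over its alternatives). Over the lung metastases Pax5, Lrat, G6pdx and Vegfa ranked in the order of the lung epithelium mean. Igj, Cd79b, Cd5l, Rbpjl and Taldo1 did not. Lung tissue as a source was not tested for these genes.

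Chance as the origin of the gene counts was tested on all 35 splits of the 8 libraries of each comparison into 4 and 4. In each of the 4 comparisons only the real split, 1 of 35, gave as many. For PDAC lung metastasis against primary the count was 2524, against at most 0 in the other splits. It was 599 against at most 59 for PDAC liver metastasis and primary, and 1279 against at most 0 for BC lung metastasis and primary. For PDAC liver against lung metastasis it was 2035 against at most 304. These free splits ignore that the tissues are matched by mouse. Among the 8 splits that part all 4 pairs of mice, the highest of the others was 0 for each, and the splits with 59 and 304 kept 2 pairs together. With the pairs parted, 1 of 8 is the smallest share that can be reached, which is too large to exclude chance. The number of BC lists called was another matter: 10 of 35 splits called at least the 11 lists of the real one, with a median of 9 and up to 16 in the others and up to 13 among those that part all pairs. Chance is therefore not excluded for the number of lists called.

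The mismatch of PDAC values and symbols was set against 2 explanations. A difference in expression between the tumour types would leave abundant genes shared, and the rank correlation of 0.1 across rows argues against it as the whole cause. The PDAC rows may keep the order of the named rows with further rows between them: the best order-keeping alignment of BC means to PDAC means left a mean squared difference of 0.677 (log2 units), against 2.5 to 2.54 for 20 alignments with BC rows shuffled within windows of 500. This fits 2 blocks with different sets of genes placed side by side in a common order. No PDAC name was taken from it, because a row's place does not identify a gene.

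On the row with the symbol Gstt1, singled out after its values were seen, the PDAC columns held 0 in all 4 primary tumours and 0.62 to 4.26 in all 8 metastases. Such a pattern was found on 26 of 37583 rows, 18 of them with a symbol beside them. As the symbols are not paired with PDAC values, this is a value of an unnamed row and not of Gstt1.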
